A study of Mus musculus with 12 samples.

How the data were processed

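Bulk RNA sequencing of MC38 tumours from mice was analysed, with 12 libraries in 4 groups of 3: isotype control, IL-21-αHSA, anti-mTIGIT and the combination. Per the labels' protocols, total RNA was extracted with TRIzol, genomic DNA was removed with DNase I, and samples that met a set RNA quality were made into Illumina libraries. The submitters' processing notes name fastp, HISAT and RSEM and the mouse build GRCm39, with no versions, roles or order. The gene annotation, the strandedness of the counting and any filters are not given in the sources used here. The authors deposited 1 table of values per gene and library. The deposited values were read as TPM, because RSEM is named and each library sums to 1000000 over all identifiers, or to 999999 in IL-21-αHSA replicate 3. Whether they were scaled by gene length was not tested. TPM are relative to each library's total and keep no read numbers, so depth is unknown and no counting intervals or count models were used.

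Columns of the table carry short names rather than the treatment labels. They were matched to the groups by wording alone: the column name that is a word for a control was taken as the only control group, the name TIGIT as anti-mTIGIT, a code name as IL-21-αHSA, and the initials of that code and TIGIT together as the combination. All 12 columns were matched, 0 were left over, and no values were used for the match. If the match were wrong, the group names would be wrong with it. The groups share replicate numbers, and no source says that a number marks a shared animal, litter or day. The submitters call the 3 samples of a group biological duplicates, and the p-values rest on the spread between them.

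The table lists 54174 identifiers, of which 474 carry the prefix of loci assembled from reads (MSTRG) and the rest are Ensembl genes. Symbols came from a GENCODE M21 table, which matched 52093 identifiers. That table is on GRCm38, not the build named for the data, so it served for names only and no coordinates are given. Identical values were held by 0 pairs of libraries.

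Genes with at least 1 TPM in at least 3 libraries were tested, 14517 in all. Values were log2-transformed after adding a pseudocount of 1. limma 3.58.1 in R 4.3.3 fitted 1 mean per group over all 12 libraries (8 residual degrees of freedom), with moderated variances, neither trend nor robust, and Benjamini-Hochberg adjustment over all genes tested at 0.05. The 6 comparisons were each treatment against isotype, the combination against each single agent, and the interaction of the agents. An exact permutation test of 3 libraries against 3 cannot give a two-sided p below 0.1, so the gene tests lean on the pooled spread.

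A total of 38 gene lists of cell types and pathways, with 683 genes of which 682 had an identifier, was fixed before the data were examined, as were the comparisons, the tests and most alternatives. Some genes belong to several lists. Lists with at least 4 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 38 lists of a comparison; camera with an estimated correlation and fry stood beside it. fry tests whether a list's genes move one way on balance and does not compare them with other genes. A member count "adjusted over the list alone" uses Benjamini-Hochberg adjustment within that list. A list's score in a library is the mean deviation of its genes from their mean over the 12 libraries. The lists described at length were taken from those with small p-values and from tissue markers, after the values were seen.

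Named genes followed a rule. Genes past the threshold came first. Since 0 passed, the 5 higher and 5 lower genes with the smallest unadjusted p in each comparison are given as values, without predicted genes, genes with a mean under 1 TPM and antigen receptor segments. To these were added Tigit, Pvr, Cd226, Il21 and Il21r against isotype, and up to 4 members of each described list with the smallest p. Of these, a part is printed. Other genes were named where few members of a list passed, and these, with S100a8, were chosen after their values were seen.

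The steps were tested on simulated data. For the combination against isotype, with 14517 genes, 20 simulated tables with normal residuals gave a recovery of 58.5% of genes changed by a log2 of 1, 91.5% for 2 and 96.5% for 3, with 203 false calls of 3487, and 20 of 20 shifted lists were found. The real data hold shared deviations between genes that the simulation lacks. The recovery of genes and lists is therefore an upper guide only. The share of false calls is not an upper limit, since it could be larger in the real data.

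Alternatives were limma-trend with robust variances, camera with an estimated correlation, fry, quantile normalization, no filter (29211 genes), a mean of at least 5 TPM (10600 genes), a pseudocount of 0.1, only the groups compared, an added log2 fold change of at least 1, an adjusted p under 0.1, the replicate number as a block, array weights, and leaving out each library. Leaving out isotype replicate 2 and IL-21-αHSA replicate 1 together, and leaving out assembled loci, were added after the data were seen. Groupings of the same libraries were refitted, 10 for each comparison of 2 groups, the real one included, and 100 drawn for the interaction.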

Results

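RNA sequencing was carried out on MC38 tumours, grown in mice from a murine colon carcinoma line, after treatment with an isotype control antibody, IL-21-αHSA, an antibody against mouse TIGIT (anti-mTIGIT), or the combination of both agents. IL-21-αHSA is named for IL-21, a cytokine that acts on lymphocytes, and TIGIT is an inhibitory receptor of T cells and NK cells. Each of the 4 groups held 3 tumour samples, which the submitters call biological duplicates, so 12 libraries were compared. Values were TPM per gene, which keep no sequencing depth, and the depth behind each value is therefore unknown. Each library had between 13408 and 14210 of 54174 listed identifiers at 1 TPM or above, and 14517 genes were tested. Pearson correlations of the log2 values lay between 0.947 and 0.976 within groups and between 0.939 and 0.979 across groups, with medians of 0.967 and 0.969. Group names of the table's columns were matched to the treatments by their wording, and all group statements rest on that match. The question behind the comparisons, as the series title gives it, was what IL-21-αHSA does in tumours together with TIGIT blockade. Values are means ± SD over 3 libraries unless stated otherwise, and fold changes are on the log2(TPM + 1) scale, which understates changes of low genes.

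The receptor targeted by the antibody, Tigit (ENSMUSG00000071552), was listed at 1.75 ± 1.04 TPM in isotype tumours, 3.21 ± 1.93 TPM with IL-21-αHSA, 3.11 ± 1.02 TPM with anti-mTIGIT and 5.92 ± 4.07 TPM with the combination. The combination mean carried 1 library at 10.59 TPM, and its log2 difference from isotype was 1.25 with an SE of 0.44 (limma adjusted p = 0.611). Pvr, which encodes the TIGIT ligand CD155, was listed at 35.5 ± 5.4 TPM in isotype tumours and between 32.4 and 37.3 TPM in the treated groups. Il21r, the IL-21 receptor gene, was at 7.66 ± 2.47 TPM in isotype tumours and at 8.06 to 9.40 TPM in the treated groups. For both genes, the treated means lay within 1 SD of the isotype mean. Cd226, encoding the activating receptor that competes with TIGIT, was below the expression minimum and not tested, with a highest library value of 1.06 TPM. Il21 was likewise not tested and was listed at 0 in 10 of 12 libraries and at 0.02 TPM in the other two.

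Tumours given IL-21-αHSA had higher values of interferon-γ response genes than isotype tumours, in all 32 measured members of that list, with a mean log2 difference of 0.93. Gbp2b (ENSMUSG00000040264), an interferon-induced GTPase, was listed at 11.4 ± 8.3 TPM against 0.853 ± 0.783 TPM, a log2 difference of 2.64 (SE 0.48, limma adjusted p = 0.794). Gbp8 was at 7.88 ± 3.37 against 2.62 ± 1.34 TPM, and Nlrc5, the transactivator of MHC class I genes, at 42.9 ± 7.2 against 24.5 ± 8.4 TPM. NK cell genes were higher in 12 of 12 members (mean log2 difference 0.64). Among them were Klrk1, encoding the activating receptor NKG2D, at 8.84 ± 1.96 against 2.89 ± 1.59 TPM, and Klrc1 at 2.83 ± 1.31 against 0.540 ± 0.322 TPM. Cytotoxic effector genes were higher in 15 of 16 members (0.77), with granzymes Gzmg at 1.63 ± 1.00 against 0.193 ± 0.261 TPM and Gzmb at 12.8 ± 5.9 against 5.07 ± 2.74 TPM. T cell inhibitory receptor genes were higher in 11 of 11 members (0.55), with Pdcd1, the gene of PD-1, at 5.57 ± 1.81 against 1.51 ± 0.77 TPM.

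T cell genes were higher in 17 of 19 members (mean log2 difference 0.61), with Cd3g at 9.91 ± 5.87 against 2.83 ± 1.79 TPM, whereas Lef1, a transcription factor of naive T cells, was lower at 5.37 ± 1.34 against 9.68 ± 0.93 TPM. MHC class II presentation genes were higher in 12 of 12 members (0.80), with H2-Eb1 at 1652 ± 772 against 730 ± 494 TPM. Endothelial genes were lower in 19 of 21 members (-0.34), with Vwf, von Willebrand factor, at 9.82 ± 1.89 against 15.4 ± 0.2 TPM. By camera with the preset correlation these 7 lists passed the threshold, and 0 of them did with an estimated correlation. They had adjusted p = 0.141 with an estimated correlation for interferon-γ response, NK cell, cytotoxic effector and inhibitory receptor genes, 0.253 for T cell, 0.309 for MHC class II and 0.438 for endothelial genes. Adjusted over the list alone, 1 interferon-γ response gene (Gbp2b), 3 NK cell genes (Klrc1, Klrd1 and Klrk1) and 1 inhibitory receptor gene (Pdcd1) passed, and 0 genes of the other 4 lists. Over all genes tested 0 passed. Without isotype replicate 2, whose neutrophil score of 2.24 set it apart, the MHC class II difference was 0.32. The interferon-γ response difference of 0.93 was 0.40 without isotype replicate 2 and IL-21-αHSA replicate 1 together, still called by the preset test (adjusted p = 0.347 with an estimated correlation). With an estimated correlation the NK cell list passed only without isotype replicate 3 (adjusted p = 0.0424). The endothelial difference was -0.60 without IL-21-αHSA replicate 1 and -0.11, no longer called, without replicate 2.

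These list-alone counts changed when 1 library was left out, also where that library belonged to another group, since the spread was estimated over all 12. For interferon-γ response genes the count was 21 without isotype replicate 3 or IL-21-αHSA replicate 2, 2 without anti-mTIGIT replicate 1, and 1 (Gbp2b) otherwise. For NK cell genes it was 1 without isotype replicates 1 or 2, IL-21-αHSA replicates 1 or 3 or anti-mTIGIT replicate 1, and 2 without anti-mTIGIT replicates 2 or 3. It was 6 without isotype replicate 3 and 5 without combination replicate 2. For inhibitory receptor genes it was 0 without isotype replicates 1 or 2 or IL-21-αHSA replicate 3, 3 without IL-21-αHSA replicate 2 and 2 without combination replicate 2. Without isotype replicate 2 and IL-21-αHSA replicate 1 together, all 3 counts were 0.

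Gene by gene, 0 of 14517 genes differed between IL-21-αHSA and isotype tumours at the adjusted threshold of limma, and likewise 0 by limma-trend. There were 472 genes with an unadjusted p under 0.05, 204 higher and 268 lower. They made up 3.25% of those tested, below the share of 0.05 that this threshold gives by chance. Among the genes with the smallest unadjusted p was Fgl2, a secreted fibrinogen-like protein of T cells and macrophages, at 25.3 ± 8.6 against 8.82 ± 2.79 TPM. Amigo2 was at 8.94 ± 1.15 against 5.45 ± 0.50 TPM, and Cst6, a cysteine protease inhibitor, was at 10.4 ± 6.0 against 2.09 ± 0.72 TPM. On the lower side, Spry1, an inhibitor of receptor tyrosine kinase signalling, was at 6.51 ± 1.98 against 13.6 ± 1.9 TPM. Gpr84, a fatty acid receptor of myeloid cells, was at 1.41 ± 0.35 against 6.31 ± 3.03 TPM, and Kcne3, a potassium channel subunit, at 4.07 ± 2.39 against 15.9 ± 7.0 TPM. Syt13 was at 0.923 ± 0.115 against 2.32 ± 0.23 TPM and Arhgap26 at 3.62 ± 0.63 against 6.17 ± 0.41 TPM. For each of these 8 genes the values of the compared groups did not overlap, which was so for 6.71% of all genes tested where chance gives 10%.

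**Figure D1:**
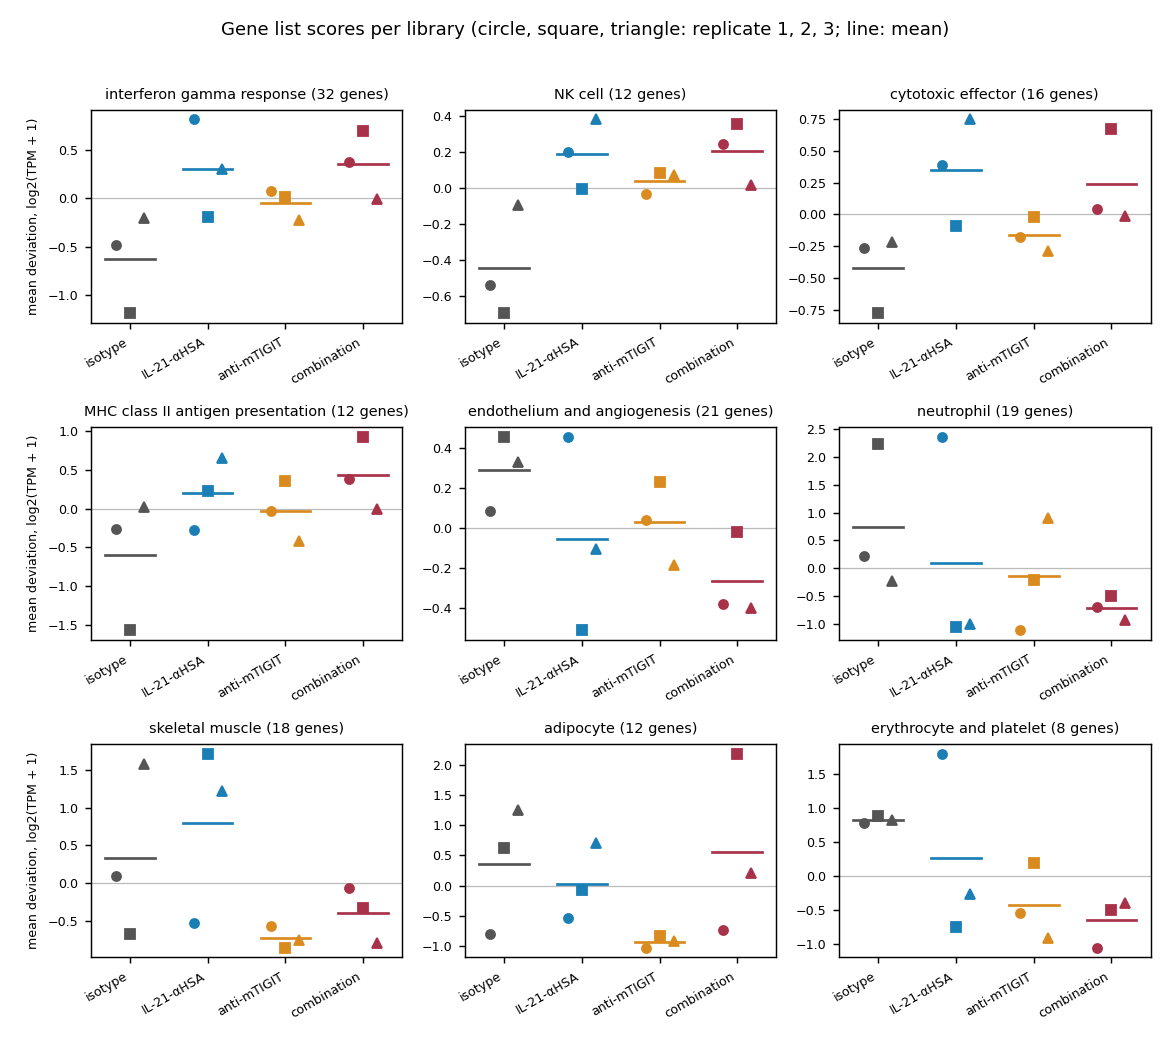
Scores of 9 gene lists in each library, as the mean deviation of the list's genes from their mean over the 12 libraries on the log2(TPM + 1) scale, by group, with 1 symbol per replicate and a line at the group mean. NK cell scores of all 9 treated libraries lie above those of the 3 isotype libraries, and isotype replicate 2 and IL-21-αHSA replicate 1 have the highest neutrophil scores, 2.24 and 2.37.

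Tumours given anti-mTIGIT also had higher interferon-γ response values than isotype tumours, in 30 of 32 members with a mean log2 difference of 0.58. Gbp2b was at 5.43 ± 1.03 against 0.853 ± 0.783 TPM and Nlrc5 at 39.9 ± 6.0 against 24.5 ± 8.4 TPM. NK cell genes were higher in 11 of 12 members (0.49), with Klrb1b, a C-type lectin receptor, at 18.99 ± 4.71 against 7.22 ± 4.91 TPM. Fibroblast and extracellular matrix genes were lower in 24 of 27 members (-0.44), with the collagen VI genes Col6a2 at 561 ± 43 against 852 ± 71 TPM and Col6a1 at 789 ± 59 against 1129 ± 87 TPM. Haemoglobin and other erythrocyte or platelet genes were lower in 7 of 8 members (-1.25). Hbb-bt was at 13.3 ± 6.0 against 57.3 ± 5.0 TPM and Alas2, the first enzyme of haem synthesis in red cells, at 0.807 ± 0.252 against 3.18 ± 0.19 TPM. Reads of the near-identical globin genes can be split between copies. Skeletal muscle genes (-1.06) and adipocyte genes (-1.28) were lower as well, in 16 of 18 and 11 of 12 members. Tnnc2, fast troponin C, was listed at 0 in all 3 anti-mTIGIT libraries and at 7.75 ± 10.58 TPM in isotype tumours, and Adipoq, adiponectin, was at 0.157 ± 0.095 against 5.32 ± 4.55 TPM.

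These 6 lists passed camera's preset test, and each had adjusted p = 0.578 with an estimated correlation. Over all genes tested 0 genes differed between anti-mTIGIT and isotype by limma and 0 by limma-trend. An unadjusted p under 0.05 was held by 507 genes, 226 higher and 281 lower. That was 3.49% of those tested, again below the share given by chance. Among the genes with the smallest unadjusted p, Fcrls, an Fc receptor-like gene of myeloid cells, was at 12.5 ± 4.5 against 39.4 ± 1.1 TPM (log2 difference -1.64, SE 0.28, limma adjusted p = 0.39). Siglec1, the macrophage lectin CD169, was at 9.72 ± 1.44 against 18.4 ± 2.6 TPM and Spry1 at 7.02 ± 1.89 against 13.6 ± 1.9 TPM. Ccdc130 was higher, at 29.4 ± 4.0 against 17.4 ± 0.7 TPM, as was Wincr1 at 13.1 ± 3.5 against 5.71 ± 1.48 TPM, and groups did not overlap for 8.06% of all genes where chance gives 10%. The microRNA gene Mir6236 was listed at 0 in the 3 isotype libraries and at 341.02, 50.31 and 340.77 TPM with anti-mTIGIT, and at 298.17 TPM in IL-21-αHSA replicate 3. Adjusted over the list alone, Klrb1b was the 1 member of these 6 lists that passed. The count was 0 without isotype replicates 1 or 2, IL-21-αHSA replicate 2, any 1 anti-mTIGIT library or any 1 combination library, and 3 without isotype replicate 3. Without isotype replicate 2 the differences were 0.30 for interferon-γ response and -0.20 for fibroblast genes, and without isotype replicate 3 they were -0.43 for muscle and -0.83 for adipocyte genes.

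Combination-treated tumours had higher interferon-γ response values than isotype tumours, in 32 of 32 members with a mean log2 difference of 0.98. Gbp2b was at 13.8 ± 7.1 against 0.853 ± 0.783 TPM, a log2 difference of 2.98 (SE 0.48, limma adjusted p = 0.319). Gbp2 was at 196 ± 42 against 81.2 ± 34.3 TPM, and Cxcl9, a chemokine that attracts activated T cells, at 110 ± 33 against 39.99 ± 25.02 TPM. Adjusted over the list alone 15 of the 32 rose, and over all genes tested 0 did. Those 15 included Gbp2b, Gbp2, Cxcl9, Cxcl11 and Cd274, the gene of PD-L1, at 17.1 ± 3.0 against 9.22 ± 1.52 TPM. Without isotype replicate 2 and IL-21-αHSA replicate 1 together, the libraries with neutrophil scores of 2.24 and 2.37, the mean difference was 0.70 and 2 members (Gbp2b and Gbp7) passed over the list alone. MHC class II genes were higher in 12 of 12 members (1.03), with H2-Eb1 at 1997 ± 906 against 730 ± 494 TPM, and 0 passed over the list alone.

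NK cell genes were higher in the combination group in 11 of 12 members (0.65), and 5 passed over the list alone: Klrk1 at 7.27 ± 1.25 against 2.89 ± 1.59 TPM, Klrb1b, Klrc1, Klrd1 and Klre1. T cell genes were higher in 17 of 19 members (0.67). Over the list alone Cd3g, at 12.3 ± 7.4 against 2.83 ± 1.79 TPM, and Cd3d rose and Lef1 fell. CD8 T cell genes were higher in 7 of 7 members (0.77), and Cd8a, at 7.003 ± 4.262 against 1.79 ± 1.07 TPM, and Cd8b1 passed over the list alone. Inhibitory receptor genes were higher in 10 of 11 members (0.66), with Pdcd1 at 6.23 ± 3.52 against 1.51 ± 0.77 TPM and its ligand gene Pdcd1lg2 at 2.36 ± 1.58 against 0.420 ± 0.165 TPM passing over the list alone. Cytotoxic effector genes were higher in 14 of 16 members (0.66), with Nkg7 at 20.78 ± 14.99 against 5.66 ± 3.34 TPM and Ifng, interferon-γ itself, at 2.40 ± 1.77 against 0.850 ± 0.171 TPM, and 0 passed over the list alone.

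Endothelial genes were lower in the combination group in 20 of 21 members (-0.56), with Emcn, endomucin, at 5.50 ± 0.71 against 10.8 ± 1.5 TPM. Cdh5, VE-cadherin, was at 13.1 ± 2.9 against 24.8 ± 3.1 TPM and the VEGF receptor gene Kdr at 4.14 ± 1.01 against 7.60 ± 1.63 TPM, and 0 passed over the list alone. Erythrocyte and platelet genes were lower in 7 of 8 members (-1.48), and over the list alone Hbb-bt, at 10.5 ± 3.3 against 57.3 ± 5.0 TPM, Hbb-bs, Hba-a1 and Alas2 fell. Neutrophil genes were lower in 19 of 19 members (-1.45), with S100a9 at 17.7 ± 7.3 against 331 ± 469 TPM, an isotype mean set by replicate 2 at 871 TPM, and 0 passed over the list alone. The 10 lists named for the combination passed camera's preset test and lost the call with an estimated correlation. They had adjusted p = 0.133 with an estimated correlation for NK cell and inhibitory receptor genes, 0.151 for interferon-γ response and cytotoxic effector genes, 0.205 for MHC class II, T cell and CD8 T cell genes, 0.289 for endothelial, 0.311 for erythrocyte and 0.523 for neutrophil genes. Without isotype replicate 2 the mean differences were 0.55 for MHC class II, 0.48 for CD8 T cell and -0.71, no longer called, for neutrophil genes. Without combination replicate 2 they were 0.38 for T cell and 0.50 for CD8 T cell genes.

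The list-alone counts of the combination changed when 1 library was left out. For interferon-γ response genes the count of 15 became 1 (Gbp2b) without isotype replicates 1 or 2, IL-21-αHSA replicate 3, anti-mTIGIT replicates 2 or 3 or combination replicates 1 or 2. It was 2 without anti-mTIGIT replicate 1, 17 without IL-21-αHSA replicate 2, 21 without combination replicate 3, 22 without IL-21-αHSA replicate 1 and 23 without isotype replicate 3. NK cell genes had 0 without isotype replicate 2 or combination replicates 1 or 2, and 4 to 6 otherwise. T cell genes had 15 without combination replicate 3, 9 without isotype replicate 3, 3 without IL-21-αHSA replicate 1, 1 without IL-21-αHSA replicate 3 and 0 without any other library. CD8 T cell genes had 0 without isotype replicates 1 or 2 or combination replicates 1 or 2, 1 without IL-21-αHSA replicate 2 or any 1 anti-mTIGIT library, and 3 without isotype replicate 3. Inhibitory receptor genes had 0 without isotype replicates 1 or 2 or combination replicate 2, and 1 without anti-mTIGIT replicates 1 or 3. They had 4 without isotype replicate 3 or IL-21-αHSA replicate 1, and 3 without IL-21-αHSA replicates 2 or 3 or combination replicate 1. Erythrocyte genes had 6 without IL-21-αHSA replicate 1, 5 without IL-21-αHSA replicate 2 and 0 without any other library. Without isotype replicate 2 and IL-21-αHSA replicate 1 together, NK cell, T cell and CD8 T cell genes each had 0. In that setting inhibitory receptor genes had 4 and erythrocyte genes 5.

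Over all genes tested, 0 genes differed between the combination and isotype by limma and 0 by limma-trend. There were 1116 genes, 7.69% of those tested, with an unadjusted p under 0.05, 304 higher and 812 lower. Pkib, an inhibitor of protein kinase A, was at 7.95 ± 1.45 against 2.41 ± 1.09 TPM, and Fgl2 at 26.5 ± 6.9 against 8.82 ± 2.79 TPM. Adamdec1 was at 8.40 ± 2.17 against 3.79 ± 0.84 TPM and Cxcr6, a chemokine receptor of tissue T cells, at 2.75 ± 0.75 against 0.777 ± 0.440 TPM. Lower values were seen for Fcrls, 12.9 ± 2.7 against 39.4 ± 1.1 TPM, and Spry1, 5.92 ± 0.18 against 13.6 ± 1.9 TPM. They were also seen for Prag1, 13.2 ± 1.8 against 24.8 ± 1.4 TPM, and the signalling adaptor Gab1, 11.1 ± 1.9 against 21.6 ± 3.4 TPM. Groups did not overlap for 13.2% of genes where chance gives 10%, and the smallest adjusted p by limma was 0.319, shared by Gbp2b, Pkib and 3 unnamed or predicted genes.

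**Figure D2:**
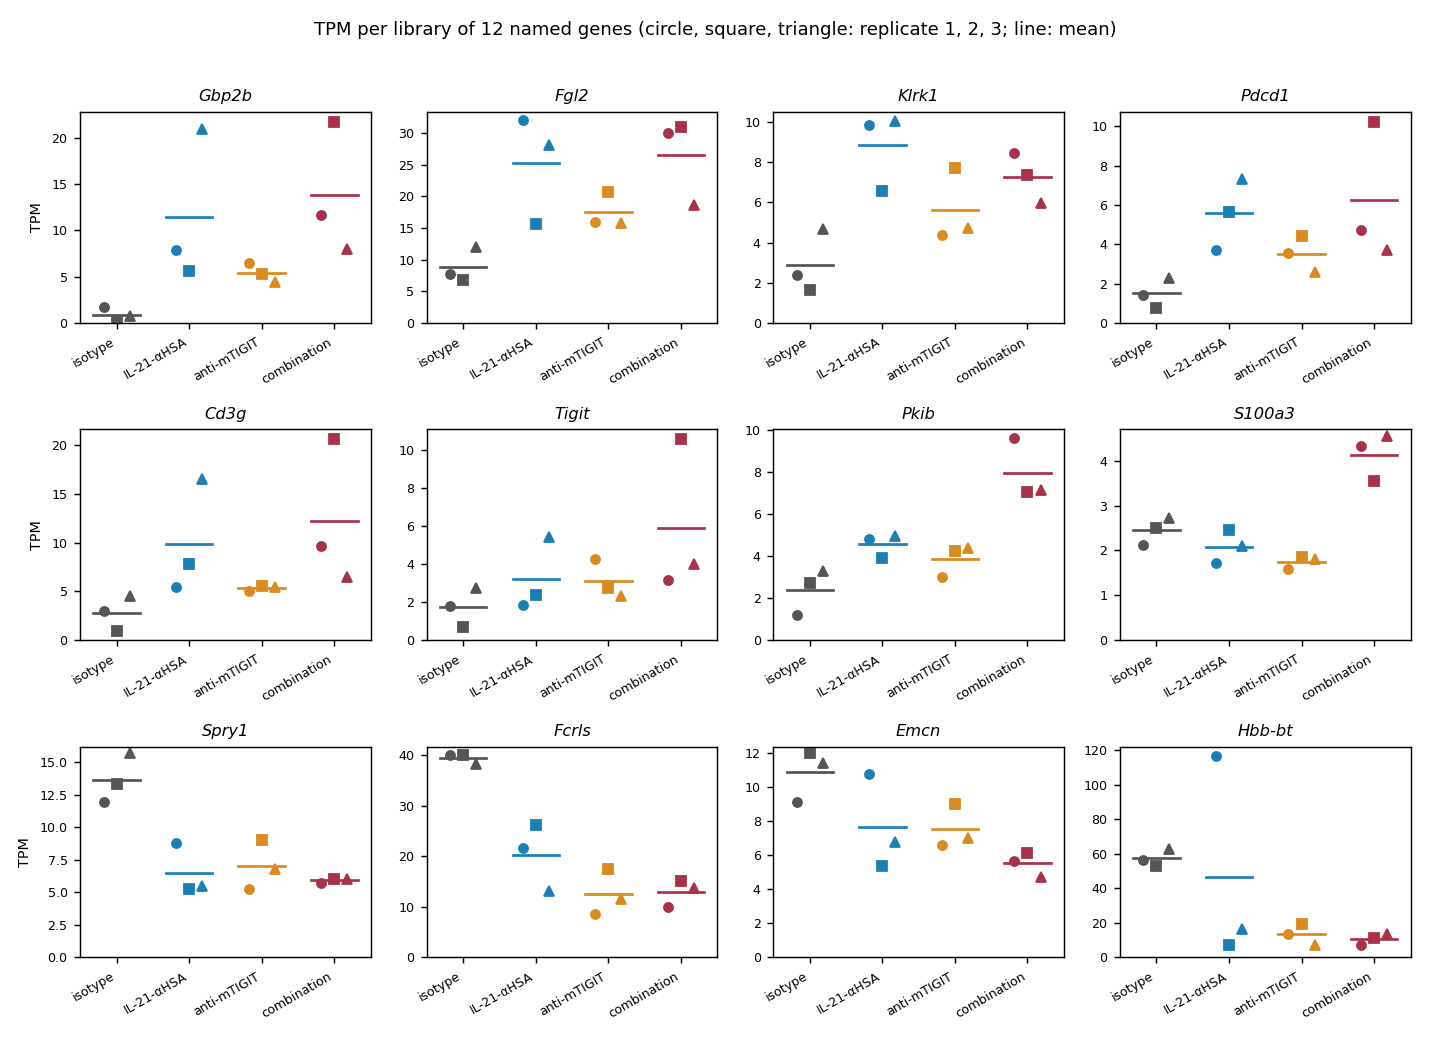
TPM of 12 named genes in each library by group, on linear axes that start at 0, with 1 symbol per replicate and a line at the group mean. Gbp2b, Fgl2 and Klrk1 have group means of 11.4, 25.3 and 8.84 TPM with IL-21-αHSA against 0.853, 8.82 and 2.89 TPM in isotype tumours, and Spry1 and Fcrls have their highest group means in isotype tumours, 13.6 and 39.4 TPM.

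Adding anti-mTIGIT to IL-21-αHSA was read from the combination against IL-21-αHSA alone. Interferon-γ response genes had 19 of 32 members higher and a mean log2 difference of 0.05 that was not called. By camera's preset test it was called without IL-21-αHSA replicate 1 (0.30) and without combination replicate 3 (0.23), where an estimated correlation gave adjusted p = 0.988 and 0.737. It was -0.20 without IL-21-αHSA replicate 2 and -0.12 without combination replicate 2. Gbp2b was at 13.8 ± 7.1 against 11.4 ± 8.3 TPM. S100a3, of the S100 calcium-binding family, was at 4.14 ± 0.53 against 2.09 ± 0.37 TPM (log2 difference 0.74, SE 0.13, limma adjusted p = 0.648), and Faim, a Fas apoptosis inhibitor, at 43.9 ± 3.5 against 32.9 ± 2.8 TPM. Cst6 was at 2.58 ± 1.23 against 10.4 ± 6.0 TPM, and Gsc, a homeobox gene, at 1.72 ± 0.38 against 3.17 ± 0.42 TPM. Skeletal muscle genes were lower in 16 of 18 members (-1.20), with Casq1, the muscle calsequestrin, at 0.270 ± 0.265 against 2.11 ± 0.84 TPM. Ribosomal protein genes were higher in 25 of 26 members by a mean of 0.10, and adipocyte genes in 12 of 12 by 0.52, with Adipoq at 9.61 ± 12.91 against 2.47 ± 2.70 TPM.

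The muscle, ribosomal and adipocyte lists were called by camera's preset test and had adjusted p = 0.761 with an estimated correlation, and 0 of their members passed over the list alone. By limma 0 genes differed over all genes tested, by limma-trend 0, and 214 had an unadjusted p under 0.05, 1.47% of those tested. The muscle difference was -1.86 without IL-21-αHSA replicate 1 and -0.74 without replicate 2, and the ribosomal call was lost without IL-21-αHSA replicate 1 (0.06). The adipocyte difference was -0.30 without combination replicate 2, 1.17 without combination replicate 1, 0.24 without IL-21-αHSA replicate 1 and 0.86 without replicate 3.

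Adding IL-21-αHSA to anti-mTIGIT was read from the combination against anti-mTIGIT alone. Interferon-γ response genes were higher in 31 of 32 members (mean log2 difference 0.40), with Gbp2b at 13.8 ± 7.1 against 5.43 ± 1.03 TPM and Irgm1, an immunity-related GTPase, at 115 ± 20 against 78.9 ± 6.2 TPM. T cell genes were higher in 17 of 19 members (0.38), with Cd3g at 12.3 ± 7.4 against 5.36 ± 0.27 TPM, and cytotoxic effector genes in 13 of 16 (0.40), with Gzma, granzyme A, at 6.90 ± 4.23 against 2.69 ± 0.33 TPM. Adipocyte genes were higher in 12 of 12 members (1.48), with Scd1, a fatty acid desaturase, at 96.18 ± 22.02 against 67.02 ± 4.49 TPM. S100a3 was at 4.14 ± 0.53 against 1.75 ± 0.14 TPM (log2 difference 0.90, SE 0.13, limma adjusted p = 0.181), and Pkib at 7.95 ± 1.45 against 3.88 ± 0.76 TPM. Gata2, a transcription factor, was at 6.74 ± 0.84 against 10.6 ± 0.7 TPM and the potassium channel gene Kcnj8 at 1.46 ± 0.42 against 3.24 ± 0.66 TPM. The pseudogene Morf4l1-ps1, whose reads can come from its parent gene, was listed at 0 in all 3 combination libraries and at 3.52, 5.64 and 3.35 TPM with anti-mTIGIT.

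The adipocyte, cytotoxic effector, interferon-γ response and T cell lists were called with the preset correlation. They had adjusted p = 0.375 with an estimated correlation for adipocyte and cytotoxic effector genes and 0.38 for interferon-γ response and T cell genes, and 0 members passed over the list alone. By limma 0 genes differed over all genes tested, by limma-trend 0, and 539 had an unadjusted p under 0.05, 139 higher and 400 lower. These 539 were 3.71% of those tested, below the share of 0.05 given by chance. Without combination replicate 2 the differences were 0.23 for interferon-γ response and 0.67 for adipocyte genes, and T cell (0.09) and cytotoxic effector genes (0.18) were no longer called. The T cell difference was 0.60 without combination replicate 3.

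Whether the effect of anti-mTIGIT differed with and without IL-21-αHSA was tested as an interaction. Among the named higher genes S100a3 had the smallest unadjusted p, with an interaction of 1.06 on the log2 scale (SE 0.18, limma adjusted p = 0.725), and Cst6 and Abhd1 were among the lower ones, at -2.50 (SE 0.56) and -0.90 (SE 0.22). Adipocyte genes had a mean interaction of 1.81 with 12 of 12 members higher, and interferon-γ response genes of -0.53 with 28 of 32 lower. NK cell genes had -0.47 with 10 of 12 lower, with Klrk1 at -1.05 (SE 0.41). By limma 0 of 14517 genes passed, by limma-trend 0, and 250 had an unadjusted p under 0.05, 1.72% of those tested. Camera's preset test called these 3 lists, each with adjusted p = 0.948 with an estimated correlation, and 0 of their members passed over the list alone. The interferon-γ response interaction was -0.25 without isotype replicate 2, -0.28 without IL-21-αHSA replicate 1 and -0.35 without combination replicate 3, the first and last no longer called. The NK cell call was lost without isotype replicate 2 (-0.34) or IL-21-αHSA replicate 3 (-0.38), and the adipocyte interaction was 0.99 without combination replicate 2.

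Across the 38 lists, camera with the preset correlation called 21 lists in IL-21-αHSA against isotype (18 higher, 3 lower), 19 in anti-mTIGIT against isotype (11 and 8), and 22 in the combination against isotype (17 and 5). It called 15 in the combination against IL-21-αHSA (9 and 6), 16 in the combination against anti-mTIGIT (15 and 1) and 5 for the interaction. With an estimated correlation, and with fry, 0 lists passed in any of the 6 comparisons. The cell cycle and epithelial tumour cell lists were called in 0 of the 6 by camera. The list of the TIGIT axis was called in 0 as well, with mean log2 differences from isotype of 0.17, 0.09 and 0.21 for IL-21-αHSA, anti-mTIGIT and the combination.

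Some libraries stood apart from their group. Isotype replicate 2 and IL-21-αHSA replicate 1 had neutrophil scores of 2.24 and 2.37 on the log2 scale where the others lay between -1.12 and 0.90, and S100a8 was listed at 469 and 440 TPM in these 2 libraries. Isotype replicate 2 also had the lowest scores for interferon-γ response (-1.19), MHC class II (-1.57), CD8 T cell (-0.94) and cytotoxic effector genes (-0.78), and IL-21-αHSA replicate 1 had the highest interferon-γ response score (0.82). Combination replicate 2 had the highest T cell (0.86) and adipocyte (2.19) scores, the erythrocyte and platelet score was highest in IL-21-αHSA replicate 1 (1.79), and skeletal muscle scores were high in isotype replicate 3 (1.58) and IL-21-αHSA replicates 2 and 3 (1.71 and 1.21).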

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

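The interaction test and the leaving out of single libraries were planned, while the regroupings of libraries, the test without isotype replicate 2 and IL-21-αHSA replicate 1 together and the tests of explanations were set down after the results were seen. Camera's preset test of the interaction called 5 lists, for which the effect of anti-mTIGIT differed with and without IL-21-αHSA. They were adipocyte (mean log2 interaction 1.81), interferon-γ response (-0.53), NK cell (-0.47), fibroblast and extracellular matrix (0.21) and mitochondrially encoded genes (0.24). With an estimated correlation each had adjusted p = 0.948. In 94 of 100 regroupings of the 12 libraries at least 5 lists were called, up to 29 in a regrouping other than the real one, so chance is not excluded for this count.

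Several of these interactions rested on single libraries. The interferon-γ response interaction was 0.01 without isotype replicate 2 and IL-21-αHSA replicate 1 together, -0.25 without isotype replicate 2, -0.28 without IL-21-αHSA replicate 1 and -0.35 without combination replicate 3. The NK cell call was lost without isotype replicate 2 (-0.34) or IL-21-αHSA replicate 3 (-0.38), and the adipocyte interaction was 0.99 without combination replicate 2. The fibroblast interaction was 0.34, -0.03 and 0.33 without isotype replicates 1, 2 and 3, and 0.48, 0.04 and 0.10 without those of IL-21-αHSA. It was 0.09 and 0.36 without anti-mTIGIT replicates 1 and 2, and 0.33, 0.14 and 0.16 without those of the combination. The mitochondrial interaction was 0.59, 0.19 and -0.05 without isotype replicates 1, 2 and 3, and 0.65, -0.13 and 0.22 without those of IL-21-αHSA. It was 0.30 and 0.13 without anti-mTIGIT replicates 2 and 3, and 0.06, 0.56 and 0.11 without those of the combination.

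The higher interferon-γ response list against isotype was the first pattern weighed. For the combination, a scaling difference between libraries is argued against, since its difference from isotype was 1.04 after quantile normalization and 0.98 before. Isotype replicate 2 as the whole source of the combination difference is argued against too. Without it 0.70 remained, above the SD of 0.35 between combination scores. For anti-mTIGIT against isotype 0.58 became 0.30 without that library, so isotype replicate 2 stays open as a source there. IL-21-αHSA itself stays open as a candidate explanation, since over 6 libraries with it and 6 without, the score was higher by 0.67 on the log2 scale (two-sided exact permutation p = 0.025 within anti-mTIGIT strata over 400 assignments, 0.158 adjusted over 38 lists) and by 0.40 without isotype replicate 2 and IL-21-αHSA replicate 1 (permutation p = 0.0833). For anti-mTIGIT the two-sided exact permutation test gave 0.31 and p = 0.215, which leaves its part undecided. The share of immune cells in each tumour piece was not measured and stays open as well.

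Neutrophil genes in isotype replicate 2 and IL-21-αHSA replicate 1 were the second pattern. Skin in the sampled piece is argued against for isotype replicate 2, whose keratinocyte score was -0.22 where the highest of the other 10 libraries was 0.16. It stays open for IL-21-αHSA replicate 1, at 1.72, although only 6 of that list's 24 genes were measured. Of 19 measured members 18, all but Mmp9, had their highest values in these 2 libraries, with S100a9 at 871 and 833 TPM against at most 242 TPM elsewhere, but this restates the pattern, so more neutrophils in those tumour pieces stay open without a test. These libraries belong to different groups, and no group of the design holds just them, so no treatment was tested as an explanation.

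The third pattern was the adipocyte list, higher in the combination than with anti-mTIGIT. Combination replicate 2 alone could be the source of part of it, since the difference of 1.48 became 0.67 without that library. What remained was above the SD of 0.09 between anti-mTIGIT scores and less than 50% of the whole difference. That SD is a narrow yardstick, since adipocyte scores of the isotype libraries ran from -0.81 to 1.25. What remained was therefore not shown to exceed the spread between tumours. The 2 combination libraries left had scores of -0.74 and 0.21 against -1.03, -0.84 and -0.92 with anti-mTIGIT, so a treatment effect and a single sample rich in fat cannot be told apart.

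For each comparison of 2 groups only 10 groupings of its 6 libraries exist, the real one included, too few for a share under 0.05. The real number of genes past the threshold was 0 in each of the 5 comparisons. Any grouping reaches 0, here 10 of 10, so this count decides nothing. The highest of the other groupings was 6 for IL-21-αHSA, 3 for anti-mTIGIT and 1 for the combination against isotype, 1 for the combination against IL-21-αHSA and 0 against anti-mTIGIT. For the number of lists called with the preset correlation, 4 of 10 groupings reached the real 21 for IL-21-αHSA against isotype (highest other 23), 1 of 10 the real 19 for anti-mTIGIT (17) and 4 of 10 the real 22 for the combination (23). Against IL-21-αHSA 5 of 10 reached the real 15 (29), and against anti-mTIGIT 4 of 10 the real 16 (21). At an unadjusted p under 0.05, 6 of 10 groupings reached the real 472 genes for IL-21-αHSA against isotype (highest other 3323), 4 of 10 the 507 for anti-mTIGIT (1270) and 3 of 10 the 1116 for the combination (1398). Against IL-21-αHSA 10 of 10 reached the real 214 (3286), and against anti-mTIGIT 5 of 10 the real 539 (1188). For genes past the threshold in the interaction, 100 of 100 regroupings reached the real 0, as any must, with 3 as the highest, and this count decides nothing either. At an unadjusted p under 0.05, 86 of 100 reached the real 250 genes, with 2535 as the highest other, so chance is not excluded for that count.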

How the results depend on the processing

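The alternatives without isotype replicate 2 and IL-21-αHSA replicate 1 together (the libraries of highest neutrophil score) and without assembled loci were chosen after the data were seen. The count of 0 genes held in all 6 comparisons under limma-trend, quantile normalization, no filter, a mean of at least 5 TPM, an adjusted p under 0.1, the fold change minimum and without assembled loci. With a pseudocount of 0.1 it was 1, 1 and 2 for IL-21-αHSA, anti-mTIGIT and the combination against isotype. With only the groups compared it was 1 for IL-21-αHSA against isotype and 2 for the combination against IL-21-αHSA. With array weights it was 1 for the combination against IL-21-αHSA, 3 against anti-mTIGIT, with S100a3 and Morf4l1-ps1 among them, and 1 for the interaction. Without both libraries of highest neutrophil score it was 2 against IL-21-αHSA and 1 (Morf4l1-ps1) against anti-mTIGIT. The cause was not tested.

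Leaving out 1 library gave 0 to 1, 0 to 2 and 0 to 1 genes for IL-21-αHSA, anti-mTIGIT and the combination against isotype, 0 to 3 and 0 to 2 for the combination against IL-21-αHSA and anti-mTIGIT, and 0 to 2 for the interaction. The libraries whose absence gave a gene were isotype replicates 1, 2 and 3 and combination replicate 2 for IL-21-αHSA against isotype. They were isotype replicate 3 and IL-21-αHSA replicate 3 for anti-mTIGIT, and isotype replicate 3 and anti-mTIGIT replicate 1 for the combination. Against IL-21-αHSA they were isotype replicates 1 and 2 and combination replicate 2, against anti-mTIGIT isotype replicate 2, IL-21-αHSA replicate 3 and combination replicate 2, and for the interaction isotype replicate 1 and combination replicate 2. A group left with 2 libraries is assumed to vary like the others.

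Libraries with the same replicate number in different groups had deviations correlated between -0.382 and 0.302 (median -0.0661, 18 pairs). Those with different numbers lay between -0.323 and 0.398 (median 0.0291, 36 pairs). No sign of pairing by number was seen, but these values cannot exclude a shared animal, litter or day. With the replicate number as a block the interaction had 1 gene and the other comparisons 0. The number of lists called, 21, 19, 22, 15, 16 and 5 in the order of the report, was 0 in each comparison with an estimated correlation and with fry. For the combination against IL-21-αHSA it was 7 with no filter, 5 with array weights and 4 without both libraries of highest neutrophil score, and for the interaction 15 with array weights and 12 without both. Leaving out 1 library gave 14 to 22, 14 to 19, 18 to 25, 4 to 21, 4 to 20 and 3 to 17 lists. The 4 came without IL-21-αHSA replicate 1 for the combination against IL-21-αHSA and without combination replicate 2 against anti-mTIGIT. The interaction had 3 without isotype replicate 2, 8 without isotype replicate 3, 15 and 9 without IL-21-αHSA replicates 1 and 2, and 17 without combination replicate 2.

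Signs turned for the adipocyte list in the combination against IL-21-αHSA, where 0.52 became -0.16 with array weights and ranged from -0.30 without combination replicate 2 to 1.17 without combination replicate 1. The fibroblast interaction ranged from -0.031 without isotype replicate 2 to 0.48 without IL-21-αHSA replicate 1, and the mitochondrial one from -0.13 without IL-21-αHSA replicate 2 to 0.65 without replicate 1, with -0.05 without isotype replicate 3. The interferon-γ response interaction was 0.007 without both libraries of highest neutrophil score. The cause was not tested. Most of the genes and many of the lists counted next were picked for small p-values in the same 12 libraries. Keeping their direction and side of the threshold was therefore likely beforehand, and the counts are a weak check. On leaving out 1 library, 820 results of genes and 404 of lists kept their direction and side of the threshold. Of the other gene results 3 came past the threshold and 5 not past it changed sign. Of the other list results 20 lost the call in the same direction, 4 with a call changed sign, 2 gained a call and 2 not called changed sign. Under the other alternatives 781 results of genes and 317 of lists kept both, 3 genes and 1 list came past the threshold, 4 genes not past it changed sign, 75 lists lost the call and 2 changed sign. TPM keep no depth, so precision beyond the spread between libraries is unknown.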

Other observations

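The tests of lists and of their members over 6 libraries with and 6 without an agent, also with 1 library left out, were chosen after the library scores had been seen, those of gene counts after the groups had been compared, and the sorting of regroupings by libraries, scores and mitochondrial share after these had been seen. Over the 6 tumours given IL-21-αHSA, alone or combined, cytotoxic effector scores were higher by 0.59 on the log2 scale, with 5 of 6 above every library without it. The two-sided exact permutation test within anti-mTIGIT strata gave p = 0.005, the smallest that its 400 assignments can give, or 0.114 adjusted over 38 lists. Gzma was at 6.58 ± 3.16 TPM (SD, n = 6) against 2.65 ± 1.33 TPM and Gzmb at 12.7 ± 6.1 against 5.67 ± 1.92 TPM, and 0 members passed over the list alone (0 to 9 with 1 library left out). The TIGIT axis score was higher by 0.14 (permutation p = 0.015, adjusted 0.114), with 6 of 6 above the median of the others. Camera's preset test did not call that list (adjusted p = 0.129). T cell costimulation genes were higher by 0.32 (permutation p = 0.01, adjusted 0.114), with Cd27 at 1.12 ± 0.52 against 0.532 ± 0.265 TPM. Cell type scores rose as well, by 0.50 for T cell (permutation p = 0.045, adjusted 0.19) and 0.57 for CD8 T cell genes (0.03, adjusted 0.163). NK cell scores rose by 0.40 (permutation p = 0.015, adjusted 0.114). The IL-21 and STAT3 response list was higher by only 0.085 (permutation p = 0.49), with 3 of 6 above the median of the others. Among the M2-associated macrophage genes, Ccl24, an eosinophil-attracting chemokine, was at 5.16 ± 3.08 against 1.53 ± 0.83 TPM and Retnla, a gene induced by interleukin-4, at 16.7 ± 15.9 against 0.602 ± 0.454 TPM. Both passed adjusted over the list alone (adjusted p = 0.028 by limma) and not over all genes tested, and that list's score was higher by 0.28 (permutation p = 0.05, adjusted 0.19). The M1-associated list rose by 0.27 (permutation p = 0.3, adjusted 0.562), so a shift particular to M2-associated genes was not shown. Over the list alone, 2 members each of the NK cell, CD8 T cell and inhibitory receptor lists also rose, and 2 of the fibroblast list fell. On leaving out 1 library Retnla still passed only without IL-21-αHSA replicate 1, anti-mTIGIT replicate 2 or combination replicate 1, and Ccl24 in these cases and without isotype replicate 1, IL-21-αHSA replicate 3 or combination replicate 2. Cd163 passed as lower without isotype replicate 1, and Chil3 without IL-21-αHSA replicate 1.

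Over the 6 tumours given anti-mTIGIT, alone or combined, erythrocyte and platelet scores were lower by a log2 difference of -1.08, with 0 of 6 above the median of the others (two-sided exact permutation p = 0.02, adjusted 0.475). Hba-a1 was at 29.8 ± 14.3 against 113 ± 83 TPM and Hbb-bt at 11.9 ± 4.6 against 52.0 ± 38.9 TPM, and 4 of 8 members fell over the list alone. IL-21-αHSA replicate 1 had a score of 1.79, while its replicates 2 and 3, at -0.76 and -0.26, were about as low as the combination libraries, at -1.06, -0.50 and -0.41. Without IL-21-αHSA replicate 1 the difference was -0.70 (permutation p = 0.035), and without combination replicate 1 it was -0.98 (permutation p = 0.075). Between the 6 libraries with and 6 without IL-21-αHSA, this list differed by -0.40 (permutation p = 0.34). That difference was -0.78 without IL-21-αHSA replicate 1 (permutation p = 0.03), with 6 members falling over the list alone. A fall particular to anti-mTIGIT was therefore not shown. For anti-mTIGIT, the number of members that fell was 0 without any 1 of the isotype libraries, anti-mTIGIT replicates 1 or 3 or combination replicates 1 or 2. Skeletal muscle scores were lower by a log2 difference of -1.13 (permutation p = 0.05, adjusted 0.605). Over all genes tested 0 of these genes passed, and 11 of 18 members fell over the list alone, among them Casq1 at 0.310 ± 0.182 against 1.84 ± 1.22 TPM and Mylpf at 3.34 ± 1.03 against 20.2 ± 17.7 TPM. That number was 1 (Casq1) without isotype replicates 1 or 3, and 0 without IL-21-αHSA replicates 2 or 3 or any 1 library given anti-mTIGIT, alone or combined. Muscle scores were high in isotype replicate 3 (1.58) and IL-21-αHSA replicates 2 and 3 (1.71 and 1.21). Isotype replicate 1 was at 0.09. Isotype replicate 2 (-0.68) and IL-21-αHSA replicate 1 (-0.54) lay within the range of the libraries given anti-mTIGIT, -0.86 to -0.06. A fall of muscle genes due to anti-mTIGIT was therefore not shown.

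Gene by gene, each agent had 0 genes past the threshold of limma over 6 against 6 libraries. There were 866 genes that had an unadjusted p under 0.05 for IL-21-αHSA (263 higher, 603 lower) and 487 for anti-mTIGIT (169 and 318). Of 100 regroupings within the other agent's strata, the real one included, 100 reached the real count of 0 for either agent, as any must. This count therefore decides nothing. The unadjusted counts were reached by 25 of 100 for IL-21-αHSA (highest other 4775) and 49 of 100 for anti-mTIGIT (4331), so chance is not excluded for them. Past the threshold the highest other count in these 100 was 2027 genes for IL-21-αHSA and 14 for anti-mTIGIT, and a regrouping with 2027 genes where the real one had 0 points to a structure of the samples. Over all 199 other groupings for each agent, the same one had the most genes past the threshold, 2027 for IL-21-αHSA and 2100 for anti-mTIGIT. It set isotype replicates 2 and 3, IL-21-αHSA replicate 1, anti-mTIGIT replicate 3 and combination replicates 1 and 3 against the other 6 libraries. Mitochondrial shares averaged 3.00% of TPM on that side and 2.01% on the other. For IL-21-αHSA the median unadjusted count was 880 genes in the 80 groupings with isotype replicate 2 and IL-21-αHSA replicate 1, the neutrophil-high libraries, on the same side. It was 368 in the 119 that part them, as the real grouping does, of which 7 reached the real 866. For anti-mTIGIT, whose real grouping has both on the same side, the medians were 616 and 389 genes. Other pairs of libraries differed more for anti-mTIGIT. IL-21-αHSA replicate 1 and combination replicate 1 had medians of 701 on the same side and 406 parted. For IL-21-αHSA replicate 3 and combination replicate 2 they were 697.5 and 406. The difference between sides rose with the unadjusted count, by rank correlation over the groupings, for several measures, among them the neutrophil score (0.489 for IL-21-αHSA and 0.358 for anti-mTIGIT), the mitochondrial share (0.386 and 0.434) and the cell cycle score (0.457 and 0.460). These measures do not single out 1 source of the structure, and RNA quality was not given for single libraries.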
